A study of Homo sapiens with 8 samples.

How the data were processed

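RNA was sequenced from 4 libraries of cells labelled KG1, 2 treated with DMSO and 2 with XX-650-23 for 12 h, and CREB chromatin immunoprecipitation from 1 library per condition after 6 h, each with an input library. Groups and replicate numbers were taken from the sample labels. Per the labels' protocols, RNA libraries were made with an Illumina TruSeq RNA kit, and chromatin was digested with micrococcal nuclease and sonicated before precipitation with a CREB antibody. Per the submitters' processing notes, TopHat2 2.0.6, HTSeq and Bowtie were used with the hg19 build. The peak caller, its threshold, the strand setting of the counting and the use of the inputs in peak calling are not given in the sources used here.

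The authors deposited whole-number read counts per gene symbol in 1 table for the 4 RNA libraries, and 18839 genes of it were used. Of its rows, 2 carried no gene name and were left out. The authors deposited 1 peak list per ChIP library, without scores. Each list gave the position of each peak and the gene or genes assigned to it. For each assigned gene it gave the signed distance in bp from that gene's start site to the peak centre. All peak starts and ends fell on a 50-bp grid, so positions were read as 1-based and closed, and a width is a multiple of 50 bp. For 99.9% of 3730 genes with 2 or more peaks the distances implied 1 start site per gene. Input libraries were not analysed here. No genome of this build was used, so motifs, GC content and gene length were not examined.

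Gene counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr at a minimum count of 10 and a minimum total of 15, which left 14221. Libraries were scaled by TMM, with factors of 0.938, 0.963, 1.049 and 1.055 for DMSO replicates 1 and 2 and XX-650-23 replicates 1 and 2. The quasi-likelihood F test was fitted to the 4 libraries with robust dispersion and no covariate, two-sided, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The biological coefficient of variation was 5.9%. SEs of log2 fold changes were taken as the fold change divided by the square root of the F statistic. CPM values were computed on the TMM-scaled library size. Top-ranked genes took little of the depth, the 10 highest holding 5 to 5.2% of the counts of a library. Neither pair of replicates agreed within sampling noise, with a chi-square per degree of freedom of 24.97 for DMSO and 3.15 for XX-650-23, so each library counted as 1 replicate.

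Gene lists were fixed before the data were examined, 34 in all, and 32 had at least 5 genes tested. They were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation and with fry. With an estimated correlation, camera uses the residual degrees of freedom, which are few with 2 libraries per group. Failing that setting therefore says little about a list whose estimated correlation is near the preset. For a list with a high estimated correlation, the p with the preset may be too small. Counts of members higher or lower were taken from the gene test, adjusted over all genes and over the list alone. Genes named in the text followed a rule fixed at the same time. It took, per direction, the 12 genes with the largest absolute log2 fold change among those past the threshold, at a mean of at least 5 CPM, with groups that did not overlap. It added up to 4 members of each list with the smallest p, and 13 genes around CREB: CREB1, CREBBP, EP300, CREM, FOS, EGR1, NR4A1, CCNA1, CCND1, BCL2, MCL1, MEIS1 and RFC3. Not all genes that the rule took are used here. Names outside the rule are given as chosen after their values were seen. Near-identical copies such as HBG1 and HBG2 or HSPA1A and HSPA1B, and overlapping or antisense genes, are uncertain because reads may be split or dropped between them.

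Peaks were compared by overlap of at least 1 bp in both directions, with exact Clopper-Pearson intervals at 95%, using Python 3.11.15 and scipy. The authors' gene assignment at any distance linked peaks to genes. A peak could be assigned to more than 1 gene, and all its assignments were used. Of 5385 gene names in the peak lists, 5060 matched a symbol of the count table and 158 more matched through synonyms of the GRCh38.p14 gene table, 96.9% in all, and no coordinates of that table were used. Higher and lower calls were compared between genes with and without peaks by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 10 tests, and by Mantel-Haenszel odds ratios over 10 bins of mean log CPM.

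The gene test was tested on simulated data with 14221 genes, the real library sizes and 200 changed genes, 50 of each size. It recovered 68% of the genes changed by 0.5 on the log2 scale, 86% of those changed by 1, 98% of those changed by 2 and 98% of those changed by 3. Of 193 genes it called, 18 were unchanged (9.3%), above the nominal rate. None of 20 unchanged lists was called. Genes were drawn independently, so this cannot show how camera behaves for correlated lists, and the estimated correlation of the ribosomal protein list was 0.86. In the data 71.6% of genes were called, so the simulation does not test the scaling under such broad change either. The overlap and odds ratio steps were also checked on simulated data. Alternatives covered scaling, filters, tests, thresholds, a replicate block, leaving out each library, overlap rules and distance limits. Leaving out 1 library left its group with a single library, which was assumed to vary like the other group.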

Results

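The data came from cells labelled KG1, an established line derived from human acute myeloid leukaemia, that were exposed to XX-650-23 in DMSO or to DMSO alone. XX-650-23 is named in the series as an inhibitor of the contact between the transcription factor CREB and its coactivator CBP. Messenger RNA was sequenced after 12 h in 2 libraries per condition. CREB-bound chromatin was sequenced after 6 h in 1 library per condition, and the 2 input libraries were not analysed here. The labels gave the dose as 5 µM in the treatment protocol and as 5 mM in the sample characteristics, and all samples had 0.1% DMSO. The RNA libraries held 58022900 and 69038564 gene counts for DMSO replicates 1 and 2, and 60617600 and 53743485 for XX-650-23 replicates 1 and 2. The peak lists held 7585 CREB peaks for DMSO and 7003 for XX-650-23. The labels did not say that the replicates were separate cultures, so p-values measured only the spread between these libraries, which may be technical.

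All 4 RNA libraries showed high erythroid transcript levels and very low levels of the MHC class II transcripts that were counted. Only 5 of 12 class II genes of the fixed list were in the count table. The fetal globin gene HBG2 ranged from 846.6 to 1724 CPM and HBG1 from 380.5 to 752.8 CPM, although these near-identical copies share reads. The embryonic globin gene HBZ ranged from 161 to 307.3 CPM, and the erythroid transcription factors GATA1 and KLF1 from 142.4 to 318.3 CPM and from 63.4 to 172.7 CPM. CD74, the invariant chain of MHC class II, was between 0.0301 and 0.11 CPM, and CIITA, the class II transactivator, was between 0 and 0.0315 CPM. The myeloid genes CSF1R and ELANE reached at most 0.0706 and 0.0367 CPM, LYZ lay between 1.86 and 2.81 CPM, and the myeloid surface gene CD33 lay between 27.3 and 35.5 CPM. GATA1 was added to these markers after the values were seen.

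**Figure D1:**
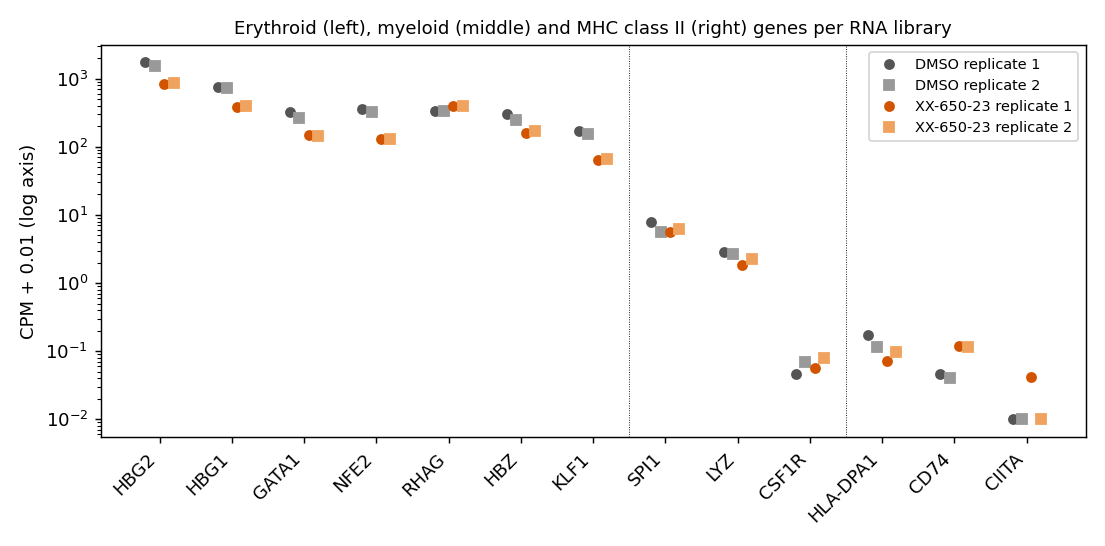
CPM (plus 0.01, log axis) of 7 erythroid, 3 myeloid and 3 MHC class II genes, with 1 point per RNA library. In every library the erythroid genes lay at or above 63.4 CPM and CD74 lay at or below 0.11 CPM.

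The first comparison asked how gene expression differed between XX-650-23 and DMSO at 12 h. Among called genes with a mean of at least 5 CPM, the largest increases were in INHBE and ADM2 and the largest decreases in AQP3 and NEFH. INHBE, an inhibin beta chain, rose by a log2 fold change of 5.89 ± 0.12 (SE, n = 2 per group), and ADM2, a peptide hormone gene, by 5.19 ± 0.14. DDIT4, an inhibitor of mTORC1 signalling, went from 45.1 ± 0.365 CPM (SD) in DMSO to 931 ± 11.8 CPM with XX-650-23. AQP3, an aquaporin, had a log2 fold change of -3.61 ± 0.1 and NEFH, a neurofilament subunit, one of -3.46 ± 0.07. HSPA1A, which encodes an inducible HSP70 chaperone, had one of -3.19 ± 0.08, going from 168.8 ± 15 to 18.5 ± 0.162 CPM, and shares reads with HSPA1B, which fell by 2.52 ± 0.09. Of 14221 genes tested, 5132 were higher and 5046 were lower with XX-650-23 at a false discovery rate of 0.05 in edgeR's quasi-likelihood test, 71.6% of the genes.

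Increases reached larger sizes than decreases. At least 2-fold changes were seen for 1703 called genes in the upward and 1263 in the downward direction, and at least 8-fold changes for 146 and 20. Other genes among the 12 with the largest increases were ALDH1L2, a mitochondrial folate enzyme (4.89 ± 0.18), TCP11L2 (4.84 ± 0.17), the stress transcription factor ATF3 (4.71 ± 0.14) and CAPN5 (4.68 ± 0.19). The glutathione-degrading enzyme CHAC1 (4.56 ± 0.15), the NKG2D ligand ULBP1 (4.56 ± 0.11), the cystine transporter SLC7A11 (4.45 ± 0.11), the netrin receptor UNC5B (4.25 ± 0.08) and the serine synthesis enzyme PHGDH (4.12 ± 0.07) completed these 12. The other large decreases were in F2RL3, a thrombin receptor (-3.45 ± 0.09), PHLDA2 (-2.77 ± 0.13), TMEM158 (-2.64 ± 0.09), RPUSD1 (-2.57 ± 0.08), WNT5B (-2.46 ± 0.13), the AP-1 gene FOSL1 (-2.44 ± 0.1), SLCO4A1 (-2.44 ± 0.08) and B4GALNT4 (-2.43 ± 0.09). The highest adjusted p among these 24 genes was 2.96e-07, for WNT5B.

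The 2 libraries of one group lay wholly above those of the other for 86.6% of the genes, against 33.3% by chance. Called genes numbered 2156 higher and 1916 lower when tested against a fold change of 1.5. Scaling by library size alone moved the median of all genes by 0.146 on the log2 scale and gave 6104 higher and 4019 lower genes, so changes are given relative to the TMM scaling. The DMSO libraries differed from each other more than the XX-650-23 libraries did, with a standard deviation of 0.171 against 0.081 in log2 difference over 10549 well-counted genes. Across those genes, which are not independent replicates, the difference of DMSO replicate 2 from replicate 1 went with the drug effect (Pearson r 0.4, Spearman rho 0.43). Both quantities hold the same DMSO libraries, so a noisier replicate 1 could by itself give part of this correlation. The size of that part was not computed.

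Amino acid response genes rose together. In a list of targets of ATF4, the transcription factor of the amino acid response, 38 of 38 tested members were higher, also when adjusted over the list alone, with a median log2 fold change of 1.76. CTH, a cystathionine-cleaving enzyme, rose by 3.69 ± 0.07 and SESN2, a leucine-sensing sestrin, by 2.87 ± 0.06. ATF4 itself went from 239.9 ± 14.5 CPM (SD) to 523 ± 12 CPM. The list's adjusted p was 8.67e-60 over 32 lists in camera with a preset correlation, and its adjusted p was 0.085 with an estimated correlation. Its median in the difference between the 2 DMSO libraries was -0.01.

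Heat shock genes fell. Of 26 tested, 20 were lower and 2 were higher, with the same counts when adjusted over the list alone, and the median was -1.14 on the log2 scale. Besides HSPA1A, the HSP40 cochaperones DNAJA1 and DNAJB1 had log2 fold changes of -2.03 ± 0.07 and -1.43 ± 0.06. The list had an adjusted p of 6.2e-14 in camera and an adjusted p of 0.42 with an estimated correlation. Genes of the endoplasmic reticulum chaperone and degradation list divided into 13 higher and 10 lower of 26, and the list did not pass (camera adjusted p 0.0529). The 4 members with the smallest p all rose: HERPUD1 by 2.34 ± 0.08, SEL1L by 2 ± 0.09, EDEM1 by 1.82 ± 0.08 and DNAJB9 by 1.66 ± 0.08. Leaving out any single library brought this list past the threshold, with an adjusted p of 0.049 without DMSO replicate 2.

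Ribosome biogenesis and DNA replication genes were also lower. Of 33 MYC and ribosome biogenesis genes, 31 fell and none rose, with a median log2 fold change of -0.98. Among them were NOP16 (-2.08 ± 0.08), MRTO4 (-1.63 ± 0.07) and RRS1 (-1.62 ± 0.07), nucleolar factors of the large ribosomal subunit, and MYC itself (-0.91 ± 0.06). Of 45 G1/S and DNA replication genes, 38 fell and 4 rose, with a median of -0.44. UHRF1, which maintains DNA methylation, changed by -1.94 ± 0.07, the flap endonuclease gene FEN1 by -1.75 ± 0.06 and the ribonucleotide reductase gene RRM2 by -1.43 ± 0.06. The counts adjusted over each list alone were the same for both. In camera the adjusted p was 9.41e-16 for ribosome biogenesis and 5.42e-08 for G1/S. With an estimated correlation the adjusted p was 0.39 and 0.32.

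Mitotic genes did not move in one direction. Of 42 G2/M genes, 11 rose, 12 fell and 19 did not pass, and 11 rose and 11 fell when adjusted over the list alone. The phosphatase gene CDC25C rose by 1.01 ± 0.07, whereas the survivin gene BIRC5 and the cyclin genes CCNB1 and CCNF had log2 fold changes of -1.16 ± 0.07, -0.9 ± 0.06 and -0.9 ± 0.06. The list had a camera adjusted p of 0.749, and its median of -0.06 became 0.09 with scaling by library size alone and 0.02 with upper-quartile factors. Library size alone gave 17 higher and 7 lower, and upper-quartile factors gave 14 and 9. Of 22 replication-dependent histone genes, most of whose transcripts lack poly(A) tails, 16 rose and 1 fell, with the same counts when adjusted over the list alone. HIST2H2BE rose by 1.66 ± 0.08 and HIST1H2AC by 1.2 ± 0.07. The histone list had a camera adjusted p of 0.00482 and an adjusted p of 0.42 with an estimated correlation. Without DMSO replicate 2 its adjusted p was 0.065.

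Cholesterol and oxidative phosphorylation genes fell. Of 26 cholesterol synthesis and uptake genes, 20 fell and 5 rose, with a median of -0.6. The sterol reductase gene DHCR7, lanosterol synthase LSS and the lipogenic regulator SREBF1 had log2 fold changes of -1.13 ± 0.06, -1.06 ± 0.06 and -1.03 ± 0.06. This list had a camera adjusted p of 0.00077 and an adjusted p of 0.42 with an estimated correlation. Of 49 oxidative phosphorylation genes, 45 fell and 1 rose, with a median of -0.51, and cytochrome c (CYCS) changed by -0.97 ± 0.06. That list had a camera adjusted p of 2.78e-05 and an adjusted p of 0.83 with an estimated correlation. Its median in DMSO replicate 2 against replicate 1 was -0.19, and its drug effect was -0.19 after the trend along that difference was removed. The counts adjusted over the list alone were the same for both lists. Of 33 glycolysis and hypoxia genes, 8 rose and 16 fell; the angiogenic factor gene VEGFA rose by 2.78 ± 0.06 and LDHA changed by -0.97 ± 0.06. The glycolysis list did not pass (camera adjusted p 0.564), and its median of -0.13 became 0.02 with scaling by library size alone.

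**Figure D2:**
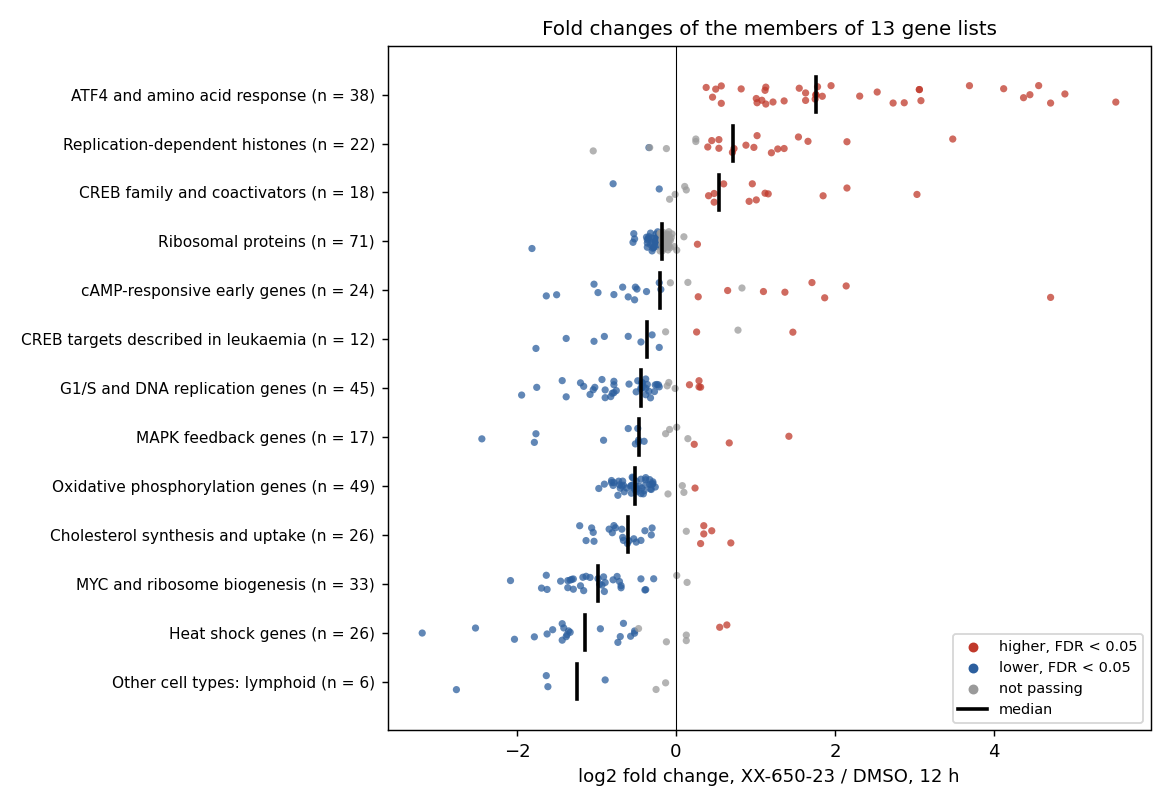
Log2 fold changes (XX-650-23 over DMSO, 12 h) of the tested members of 13 gene lists, 1 point per gene, coloured by the edgeR call, with black bars at the list medians. The 10 lists that passed camera with a preset correlation are drawn with 3 that did not: CREB targets described in leukaemia, cAMP-responsive early genes and ribosomal proteins. Medians ran from -1.25 in the lymphoid list to 1.76 in the ATF4 list.

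Transcripts in the list of the CREB family and coactivators mostly rose. Of 18 tested, 12 were higher, 2 were lower and 4 did not pass, with a median of 0.54 and the same counts adjusted over the list alone. Removing the trend along the DMSO difference moved the median of its well-counted members from 0.5 to 0.29 ± 0.16 (SE). CREBRF, a regulator of CREB3 that is in the list but is not itself a CREB family member, rose by 3.03 ± 0.1. ATF5 rose by 1.85 ± 0.07, ATF7 by 1.16 ± 0.07 and ATF4 by 1.12 ± 0.07. ATF4, whose target list is described above, is thus also a member of this list. CREBBP, which encodes CBP, rose by 0.92 ± 0.09, CREB1 by 0.48 ± 0.08 and EP300 by 0.48 ± 0.14. CREM, which encodes a cAMP-responsive modulator, changed by -0.21 ± 0.07. EP300 missed the threshold in DESeq2, and CREM missed it with upper-quartile factors, with library size alone and without either XX-650-23 replicate. The list had a camera adjusted p of 0.00033 and an adjusted p of 0.39 with an estimated correlation.

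CREB targets described in leukaemia were mostly lower, but the list did not pass. Of 12 tested, 8 fell and 2 rose, also when adjusted over the list alone, and the camera adjusted p was 0.0842. Cyclin D1 (CCND1) changed by -1.76 ± 0.08, PCNA by -1.38 ± 0.07, FOS by -1.03 ± 0.16, EGR1 by -0.6 ± 0.07, the replication factor gene RFC3 by -0.44 ± 0.07 and MCL1 by -0.3 ± 0.06. The antiapoptotic gene BCL2 instead rose by 1.47 ± 0.08, and MEIS1 had a log2 fold change of 0.78 ± 0.43 (adjusted p 0.126). CCNA1 was not analysed here. Of 24 cAMP-responsive early genes, 8 rose and 13 fell, also when adjusted over the list alone. ATF3, KLF6 (1.87 ± 0.08) and JUN (1.71 ± 0.07) were among those that rose, and NR4A1 had a log2 fold change of 0.15 ± 0.14 (adjusted p 0.366). The median of the cAMP list was -0.2 and its mean 0.22, and it did not pass in camera (adjusted p 0.618, upward). Of 17 MAPK feedback genes, 10 fell and 3 rose, also when adjusted over the list alone. That list passed in camera with an adjusted p of 0.0479, which was 0.59 with an estimated correlation, 0.057 without DMSO replicate 1 and 0.082 without DMSO replicate 2.

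Apoptosis genes of the BCL2 family changed in both directions, with 6 of 14 higher and 8 lower. The BH3-only genes BBC3 and PMAIP1 rose by 2.53 ± 0.08 and 1.22 ± 0.07, and BOK changed by -1.31 ± 0.08. The median of this list was -0.25, its mean was 0.27 and its camera adjusted p was 0.749. Of 19 p53 targets, 8 rose, 6 fell and 5 did not pass. The death receptor gene TNFRSF10B rose by 2.05 ± 0.09 and AEN changed by -1.43 ± 0.07, and the list had a camera adjusted p of 0.278. Of 31 autophagy and lysosome genes, 20 rose and 10 fell, among them WIPI1 (1.94 ± 0.07) and ULK1 (1.06 ± 0.07), with a camera adjusted p of 0.0951, which was 0.025 without DMSO replicate 1. The counts for these 3 lists were the same when adjusted over each list alone.

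Genes of other cell types also moved. Of 14 erythroid genes tested, 8 fell and 2 rose, with a median of -0.77. HBG1 and HBG2 both changed by -0.93, with SEs of 0.06 and 0.07, and KLF1 by -1.35 ± 0.07. The erythroid list had a camera adjusted p of 0.0842 and a median of -0.15 in the difference between the DMSO libraries. Without 1 library at a time its adjusted p ran from 0.0037 to 0.047. Of 6 lymphoid genes, 4 fell, among them CD3D, a T-cell receptor subunit gene, from 59 ± 8.68 to 19.4 ± 0.0515 CPM (SD). The lymphoid list had a camera adjusted p of 0.0479 and an adjusted p of 0.59 with an estimated correlation. Without DMSO replicate 1 it was 0.18 and without DMSO replicate 2 it was 0.14. Of 11 epithelial or fibroblast genes, 5 fell and 1 rose, and KRT8, a keratin, lay between 176.6 and 325.8 CPM. Of 15 myeloid differentiation genes, 8 rose and 4 fell, and CD33 rose by 0.32 ± 0.07. Of 13 stem and progenitor genes, 5 rose and 3 fell; RUNX1 rose by 1.28 ± 0.07 and LMO2 changed by -1.76 ± 0.07. The epithelial, myeloid and progenitor lists had camera adjusted p-values of 0.34, 0.748 and 0.749.

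None of the 10 lists that passed in camera did so with an estimated correlation, where 4 lists had an unadjusted p under 0.05. The estimated correlation was 0 for the ATF4 list, -0.01 for G1/S and -0.02 for the CREB family, against the preset 0.01. For these lists the few degrees of freedom, not a higher correlation, raised the p. The estimated correlation was 0.29 for heat shock and 0.7 for oxidative phosphorylation. For these 2 lists the p with the preset may be too small. The fry test, which asks only whether a list's genes moved one way, passed 21 of 32. The remaining lists did not pass in camera. Of 71 ribosomal protein genes, 32 fell and 1 rose, and 23 fell when adjusted over the list alone. With upper-quartile factors 17 fell, and with library size alone 9 fell and 3 rose, with a median of -0.03. Their median in the main test was -0.18, the median of the 70 well-counted ones in the DMSO difference was also -0.18, and the camera adjusted p was 0.0842. It ran from 3.6e-05, without DMSO replicate 2, to 0.26, without DMSO replicate 1, when 1 library was left out. Of 33 DNA repair genes, 11 rose and 13 fell, with MSH6 at -0.65 ± 0.06 and RAD50 at 0.75 ± 0.07. Of 27 NRF2 oxidative stress genes, 11 rose and 12 fell, with GCLC, which makes glutathione, at 1.44 ± 0.07 and PRDX1 at -0.94 ± 0.07. Of 24 interferon-stimulated genes, 10 rose and 5 fell, with BST2 at -1.25 ± 0.08. Of 23 NF-kB and chemokine genes, 7 rose and 7 fell, with TNFAIP3, a feedback inhibitor of NF-kB, at 2.82 ± 0.11. The fatty acid synthesis, cholesterol efflux, metallothionein, xenobiotic and megakaryocyte lists held 5 or fewer genes in the higher direction and 6 or fewer in the lower, and their camera adjusted p-values ran from 0.748 to 0.808. Adjusted over each list alone, 12 NRF2 genes rose and 12 fell and 2 progenitor genes fell, and the other counts in this and the preceding paragraph were the same. The mean and the median differed in sign for the BCL2 family, cAMP, cholesterol efflux, DNA repair and NRF2 lists. Of 12 MHC class II genes in the fixed list, 5 were in the count table and only 2 were tested. No list test was made for them.

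The second comparison asked which CREB peaks were seen both with DMSO and with XX-650-23 at 6 h. CREB peaks lay mainly at promoters in both lists, and about as many were shared as were not. Of the 7585 DMSO peaks, 3987 overlapped an XX-650-23 peak by at least 1 bp, a share of 52.6% (95% Clopper-Pearson interval 51.4 to 53.7%). Of the 7003 XX-650-23 peaks, 4026 overlapped a DMSO peak, a share of 57.5% (56.3 to 58.7%). Shifting the DMSO peaks by 10 to 500 kb left a median of 0.39% shared over 20 shifts. With 1 library per condition there was no replicate spread to set a difference against, and the intervals cover counting error only. Requiring 50% of both peaks lowered the shares to 36.8% and 39.9%.

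Sharing depended on peak width. Of the DMSO peaks that were 50 bp wide, the smallest width, 11.6% were shared, against 98.1% of those of 401 to 800 bp and 100% of the 511 wider ones. For XX-650-23 the values were 17.2%, 97.8% and 100% of 436. Peaks over 400 bp without a counterpart numbered 18 of 1473 for DMSO and 20 of 1350 for XX-650-23. The median width was 150 bp in both lists, and the peaks covered 2.13 Mb for DMSO and 1.91 Mb for XX-650-23. The widest peak of both lists lay by NUP214, a nuclear pore gene (hg19 chromosome 9, 134000251 to 134004500 for DMSO and 134000001 to 134005300 for XX-650-23), and the next by TBP, the TATA-binding protein gene. Peaks carried no scores, so these were chosen by width after the values were seen.

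**Figure D3:**
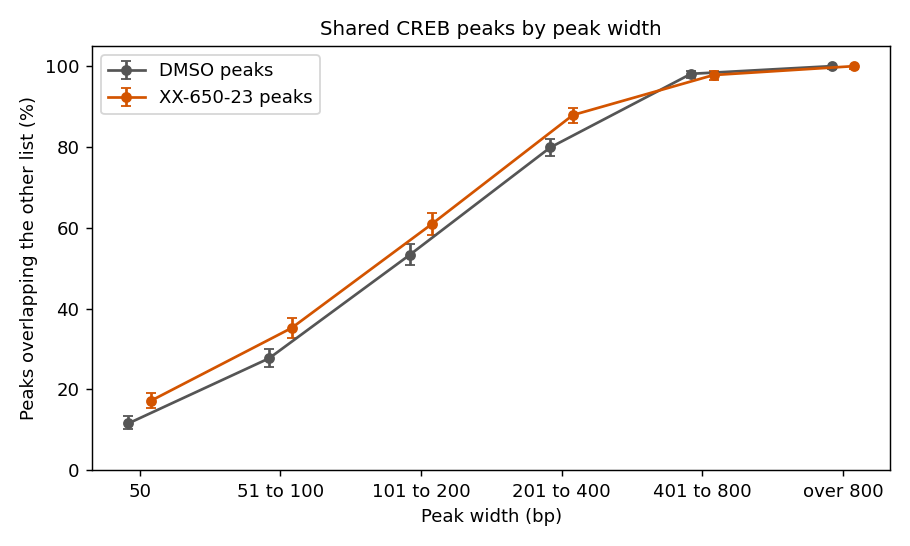
Share of CREB peaks (%) that overlapped a peak of the other list, by peak width (bp), for the DMSO and XX-650-23 lists, with 95% Clopper-Pearson intervals. The share rose from 11.6% and 17.2% at 50 bp to 100% above 800 bp in both lists.

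By distance to the nearest transcription start site, as the authors assigned it, 57.9% of DMSO and 55.8% of XX-650-23 peaks had their centre within 1 kb. Within 200 bp of a start site, DMSO had 653 peaks without an XX-650-23 counterpart and XX-650-23 had 314 without a DMSO counterpart. Between 1 and 5 kb the order was opposite, with 762 for DMSO and 959 for XX-650-23. CREM had a shared peak 384 bp upstream of its start site (chromosome 10, 35415851 to 35416150 for DMSO), and RFC3 had one at 205 bp upstream (chromosome 13, 34391601 to 34392400 in both lists). FOS had shared peaks 680 and 155 bp upstream in the DMSO list, EGR1 had one at 180 bp upstream and PCNA had one 71 bp downstream. ATF4 had a 300-bp DMSO peak 268 bp upstream (chromosome 22, 39916151 to 39916450), and NR4A1 had a 50-bp DMSO peak 410 bp upstream (chromosome 12, 52444751 to 52444800). Neither of those overlapped an XX-650-23 peak. CD74, whose RNA was near 0, had a 1600-bp DMSO peak 2348 bp downstream of its start site (chromosome 5, 149789351 to 149790950) that was shared. HLA-DRA had a shared 950-bp DMSO peak 343 bp upstream (chromosome 6, 32406801 to 32407750). CD74 and HLA-DRA were chosen for this comparison after their peaks were seen.

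The third comparison asked whether genes with a CREB peak changed more often in expression. Genes assigned a DMSO peak were more often lower with XX-650-23 than other genes, and about equally often higher. Of 4368 tested genes with a DMSO peak, 41.3% were lower, against 32.9% of 9853 without one, an odds ratio of 1.43 (Fisher's exact test, two-sided, adjusted p 6.7e-21 over 10 tests). Higher genes made up 35.4% and 36.4%, an odds ratio of 0.96 (adjusted p 0.291). Genes with a peak in both lists were lower in 42.8% of 3331 cases, against 32.7% of 9268 genes with a peak in neither (odds ratio 1.54, adjusted p 5.23e-24). Genes with a DMSO peak only were lower in 36.5% of 1037 cases, an odds ratio of 1.18 against genes with neither (adjusted p 0.0408). They were lower less often than genes with shared peaks (odds ratio 0.77, adjusted p 0.00101). Among 585 genes with an XX-650-23 peak only, 40.2% were higher and 36.2% lower, and neither share passed against genes with a peak in neither list (adjusted p 0.102 and 0.121). This depended on the distance limit. With peaks within 5 kb only, 40.4% of 428 such genes were lower, against 32.6% with neither (odds ratio 1.4, Fisher adjusted p 0.00229). For DMSO-only genes that odds ratio was 1.24 (adjusted p 0.00615). Higher genes did not pass for XX-650-23 only (adjusted p 0.645).

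Genes with shared peaks were more highly expressed, with a median of 5.82 log2 CPM against 3.57 for genes with a peak in neither list. Compared within 10 bins of mean expression, the excess of lower genes among those with a DMSO peak was not seen, and the Mantel-Haenszel odds ratio was 0.93 (95% interval 0.86 to 1.01, p 0.0853). For higher genes it was 1.04 (0.96 to 1.13, p 0.327). Median log2 fold changes were -0.04 with a DMSO peak and 0.05 without. Genes are not independent replicates, so these p-values describe the lists only, and the peaks were measured at 6 h and the transcripts at 12 h.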

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

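The distance limit of 5 kb, distance limits within expression bins, the width minimum, the 500-bp gap and the removal of the DMSO trend were chosen after the data were seen; the other settings were fixed before. The counts of higher and lower genes stayed within 1.5 times of 5132 and 5046 under every scaling, filter and tool and without any single library (4284 to 6104 higher, 4019 to 5457 lower). They were 2156 and 1916 against a 1.5-fold change, which asks more of each gene. No gene was called in opposite directions by any of these. Library size alone gave 60.3% higher calls against 50.4%. Replicate numbers shared by the groups said nothing of a shared day, and with the replicate block 5323 genes were higher and 5176 lower. Replicate 2 minus replicate 1 correlated at 0.22 across genes between the groups. Of 152 genes taken by the naming rule, 145 kept their direction and side of the threshold in every setting that tested them other than the 1.5-fold test, which ended the call of 27; the filter at 1 CPM tested 147. Without XX-650-23 replicate 2, HLA-DMA, never called, had a log2 fold change of -0.02 in place of 0.61.

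Of the gene lists, 10 passed in camera and 21 in fry, which tests another null. With an estimated correlation, which leaves few degrees of freedom here, 0 passed, at adjusted p-values of 0.085 or more. The replicate block brought in the endoplasmic reticulum (0.022), erythroid (0.031) and ribosomal protein (0.031) lists and ended no call, and library size alone brought in the first of these (0.04). Without 1 library at a time, endoplasmic reticulum and erythroid passed in all 4 cases, ribosomal protein in 3 and autophagy in 1. The lists for DNA repair and megakaryocytes, never called, changed direction without DMSO replicate 2 (adjusted p 0.92 for both; 0.68 to 0.92 and 0.92 to 0.95 without 1 library at a time). Removing the trend along the DMSO difference moved the oxidative phosphorylation median from -0.49 to -0.19 and that of the CREB family from 0.5 to 0.29.

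Peak sharing was 84.7% of DMSO and 90.1% of XX-650-23 peaks for peaks of at least 200 bp, where wider peaks were more often shared. By construction of the rules, sharing was lower at 50% of both peaks (36.8% and 39.9%) and higher with a gap of up to 500 bp (69% and 75.7%). It stayed within its interval for centres within 200 bp and on chromosomes 1 to 22 and X. Score-based alternatives were not run because the lists held no scores. The odds ratio for lower genes with a DMSO peak ran from 1.38 to 1.61 without 1 library at a time and was 1.58 within 1 kb, but 0.93 within expression bins (1 within 1 kb and 0.97 within 5 kb), where the difference in expression between genes with and without peaks is removed. For higher genes it was 0.96, and 1.04 within expression bins, 1.09 at a false discovery rate of 0.01, 1.03 to 1.08 without 1 library at a time, 0.87 within 1 kb and 0.9 within 5 kb, the last 2 past the threshold. Within expression bins those 2 were 0.94 and 0.97 and did not pass; the cause of the other changes was not tested. Gene counts per library ran from 53743485 to 69038564, and the peak lists gave no depth.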

Other observations

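All tests here except those on 10 further erythroid genes and on the narrowest peaks were chosen after the results were seen. Outside the fixed lists, 9 gene families were picked by name after the values were seen and tested with camera over 41 lists; 8 passed, and none did with an estimated correlation. Splicing factors of the SR family fell in 10 of 11 tested members, with SRSF2 at -1.88 ± 0.06, SRSF3 at -1.76 ± 0.06 and SRSF7 at -1.5 ± 0.06 (log2 fold change, SE; adjusted p of the family 3.4e-07, 0.38 with an estimated correlation). Mitochondrial ribosomal protein genes fell in 67 of 77 and proteasome subunit genes in 33 of 36, with medians of -0.66 and -0.61, and all 8 CCT chaperonin genes fell (adjusted p 8.53e-11, 6.78e-07 and 0.00116, and 0.66, 0.61 and 0.61 with an estimated correlation). Once the trend along the DMSO difference was removed, the medians of the well-counted members of these 4 families went from -0.79, -0.65, -0.61 and -0.7 to -0.71, -0.34, -0.34 and -0.48. Tubulin genes fell in 12 of 16, with TUBB4B at -2 ± 0.07, hnRNP genes in 15 of 20 and RNA polymerase I and III genes in 10 of 15 (adjusted p 2.93e-05, 0.00116 and 0.00614, and 0.48, 0.38 and 0.38 with an estimated correlation); the medians of their well-counted members went from -0.86, -0.43 and -0.39 to -0.69, -0.24 and -0.42 without the trend. Of 428 ZNF zinc finger genes, 237 rose and 74 fell (adjusted p 0.000483, and 0.46 with an estimated correlation), with a median of 0.41; for the 335 well-counted ones it went from 0.33 to 0.21 without the trend. Genes with EIF symbols, mostly translation initiation factors but also eIF2-alpha kinases and eIF4E-binding proteins, went both ways, with 14 higher and 26 lower of 49, and did not pass (adjusted p 0.0509). The noncoding RNAs GAS5 and SNHG1 rose by 1.05 ± 0.06 and 1.04 ± 0.06.

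At matched expression, DMSO peaks of CREB within 5 kb of start sites were more frequent in 4 of the fixed lists. Of 24 cAMP-responsive early genes, 14 had a DMSO peak, 58.3% against 20.6% for genes of the same expression bin (Mantel-Haenszel adjusted p 9.38e-05 over 32 lists). Of 22 histone genes, many of them neighbours, 16 had one, 72.7% against 16.3% (4.42e-12). Ribosomal protein genes had one in 49 of 71, 69% against 48.8% (0.0133), and G2/M genes in 28 of 42, 66.7% against 42% (0.0142); in these 4 lists 12, 15, 47 and 24 genes had an XX-650-23 peak. Of 26 endoplasmic reticulum chaperone and degradation genes, 17 had a DMSO peak and 17 an XX-650-23 peak, 65.4% for DMSO against 38.7% (0.0516). Of 27 NRF2 genes, 4 had a DMSO peak, 14.8% against 40.2%, and 8 an XX-650-23 peak (0.0524 for DMSO). Neither list passed. Genes of the ATF4 list, all of which rose, had one in 14 of 38, 36.8% against 42.2% (0.828), and heat shock genes in 12 of 26, 46.2% against 40.8% (0.867). Of 2651 genes with a peak within 1 kb in both lists, 20 were below 0.1 CPM, 0.75% against 22% of all genes. Among them were CD74 and the ribosomal protein gene RPL21 (0.0116 CPM), so a value near 0 did not by itself show that a gene was silent.

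The RNA libraries were labelled KG1, a line described as myeloid and positive for MHC class II. They had globin, GATA1 and KLF1 transcripts at 63.4 CPM or more. Class II transcripts in the count table were almost absent, but only 5 of 12 class II genes of the fixed list were in it. Genes of other cell types were present, with KRT18 at 195.4 to 307.4, EPCAM at 89.8 to 147.9 and CD3D at 19.4 to 65.2 CPM. The myeloid gene SPI1 lay between 5.57 and 7.9 CPM. A minor share of erythroid cells mixed into class II positive cells was argued against by CD74, one of the most abundant transcripts of such cells, which reached only 0.11 CPM. The value of CD74 alone would not settle this, but HLA-DPA1, HLA-DPB1, HLA-DMA and CIITA also reached at most 0.406 CPM. Loss of reads from polymorphic HLA genes was argued against by CIITA, which is not an HLA gene and reached 0.0315 CPM. This cannot speak for the class II genes that were not in the count table. Of 10 further erythroid genes named before their values were looked at, 8 lay above 5 CPM in every library, at 36.45 CPM or more. ANK1 lay at 254.7 CPM or more, and TRIM10 and TSPO2 gave no value. By mean CPM, SPI1 ranked 9743 of 18839 genes. A limit of 5 CPM is thus passed by many genes and does not by itself mark a cell type. The high globin, GATA1 and KLF1 values would go with RNA of an erythroid type of cell, either another line or a changed one. Which of these it was, and whether the ChIP libraries, with CREB peaks at CD74 and HLA-DRA, came from the same cells, stays open, and no biological explanation was tested.

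The difference between the DMSO libraries went with the drug effect, from a median drug effect of -0.4 in the lowest of 10 equal bins of that difference to 0.6 in the highest. Both hold the same DMSO libraries, and the part of this trend that shared noise would give was not computed. As the whole cause of the ATF4 and heat shock changes, this trend was argued against by their medians. These went from 1.74 to 1.78 and from -1.34 to -1.09 for well-counted members once it was removed. Both lists lay near the centre of the DMSO difference (medians -0.01 and -0.05), so its removal could move them little and cannot speak for other lists. The oxidative phosphorylation median, at -0.19 in that difference, went from -0.49 to -0.19. The ribosomal protein median went from -0.18 to 0.15, so its direction may come from the trend. A weak drug-like response in DMSO replicate 2 was argued against by the ATF4 list, whose median in the DMSO difference was -0.01 ± 0.02 (SE) where the overall slope would give 0.16. RNA quality and library preparation stay open as sources of the trend.

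Narrow peaks of one condition often had no counterpart in the other. Loss of CREB from well-covered sites with XX-650-23 was argued against by peaks over 400 bp, of which 1.2% lacked a counterpart for DMSO and 1.5% for XX-650-23; width stands in for coverage here, and a lower signal at shared sites was not tested. Of the 50-bp DMSO peaks, 36.2% had an XX-650-23 peak within 500 bp, against 99.5% of those over 400 bp, and the values for XX-650-23 were 45.8% and 99.7%. Calling near the threshold in single libraries and a change of CREB at weak sites would both give these values and cannot be told apart without replicates or scores. The excess of DMSO peaks without a counterpart within 200 bp of start sites, 653 against 314, has no replicate to set it against and stays open.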
